A study of Homo sapiens with 18 samples.

How the data were processed

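Total RNA isolated with the Qiagen miRNeasy kit had been labelled with the 3' IVT Express kit and hybridised to Affymetrix HGU133A 2.0 arrays, which were read on a GeneChip scanner under Command Console. Per the labels, the authors produced log2 values in GeneSpring GX 12.1 with its default settings. The deposited log2 values of each of the 22277 probe sets had a median of 0 over the 18 arrays. They give a probe set's level relative to its own median and carry no absolute level. They ran from -10.65 to 11.66, and 35.0% of the probe sets (7797) had a standard deviation (SD) under 0.05 over the arrays. The series holds these values in 2 tables, which were identical (largest difference 0). The raw array files were not analysed here.

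Of the probe sets, 62 Affymetrix controls, 583 assigned to several genes and 1258 assigned to no gene were left out of the gene tests. The remaining 20374 probe sets, each with exactly 1 gene, gave 12750 genes. Because no levels exist, the brightest probe set of a gene could not be picked, and a gene's value was the mean of its probe sets (8125 genes had 1 probe set and 4625 had more). Gene names were brought up to date through the Entrez identifiers of 20226 probe sets, which changed 1672 symbols. Coordinates are those of the array annotation, whose genome build is not named in the sources used here. No dim genes were filtered out.

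Groups were read from the labels. Each line had 3 parental arrays, 3 arrays after 72 h with the compound and 3 arrays of resistant clones. The labels name clones C1, C4 and CP in TC32 (resistant replicates 1, 2 and 3) and C3, C4A and C5 in TC71 (likewise). Resistant clones had been selected in rising doses up to 3 µM over 7 months, and the labels do not say whether the compound was present at harvest. They also do not say whether replicates were separate cultures, so p values measure only the spread between arrays.

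All 8 comparisons came from 1 limma model of the 6 group means with moderated tests (residual degrees of freedom 12, prior 0.83). The model takes 1 spread per gene for all 6 groups. Adjusted p is the Benjamini-Hochberg value over the 12750 genes, with a threshold of 0.05. "Rose" and "fell" are used for genes past that threshold. Interactions are the change in TC32 minus the change in TC71. Gene overlaps between lines were tested with a one-sided Fisher exact test. The correlation between 72 h and resistant changes of a line was set beside 100 simulations of unchanged groups that share the parental arrays, since the parental arrays enter both.

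The 19 gene lists came from general knowledge. They were EWS-FLI1 activated targets, EWS-FLI1 repressed targets, G2/M and mitosis, S phase and DNA replication, p53 targets, drug transporters and detoxification, unfolded protein and integrated stress response (below, stress response), cholesterol synthesis, heat shock, interferon response and antigen presentation, extracellular matrix and mesenchymal genes, neuronal genes, tubulins and microtubule-binding proteins, splicing factors and fusion partners, immediate early genes, apoptosis regulators, hypoxia and glycolysis, cytosolic ribosomal proteins, and markers of other cell types. Lists were tested with camera (limma) with a preset correlation between genes of 0.01 and adjusted over the 19 lists of a comparison. The same test with an estimated correlation is given beside it. Members past the threshold are counted over all genes and also adjusted over the list alone.

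The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule takes, from each comparison with parental arrays, the 5 largest rises and 5 largest falls among genes that passed and whose 2 groups of arrays did not overlap. It adds the 2 passing members with the largest change of each list with at least 3 passing members. Each comparison of resistant with 72 h arrays gives 3 rises and 3 falls, and each interaction gives 3 values on either side. A few genes that the rule gives are not reported here. Genes always given include DHX9, EWSR1, FLI1, ABCB1 and CCND1.

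Other settings chosen before the data were examined were quantile normalization applied again, centring on each array's median, every probe set on its own, probe sets without the suffixes _x_at and _s_at (which mark probes shared between transcripts), empirical Bayes with trend and robust settings, array weights, a fit of the compared groups alone, replicate number as a block, stricter thresholds and leaving out each array. Array weights were estimated gene by gene on genes with an SD of at least 0.1, because the default estimate did not converge. The other table was identical and gave nothing new, and a filter on the mean level could not be run without levels. Chosen after the values were seen were the probe set with the largest SD, a filter on SD, a set of 4 arrays left out, the average of TC71 72 h replicates 1 and 3, and leaving out arrays for gene lists, for DHX9 between clones and 72 h, for 3 RFPL genes and for the interactions of genes named in 1 line.

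The pipeline was tested on simulated normal noise that took each gene's residual spread from these arrays. The spread was equal in all groups and the genes were independent. Of genes given a 2-fold change, 77% were recovered in the TC32 72 h comparison, 74% in TC71, 81% in resistant TC32 and 75% in resistant TC71. Of 4-fold changes, 95%, 92%, 94% and 97% were recovered, and 5.5%, 5.1%, 7.4% and 5% of calls were false. A list shifted by -0.50 was found by camera with an adjusted p of 1.14e-31, and 0 other lists were called. Since the simulated genes were independent, this does not show how camera performs on lists whose genes move together. Programs were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.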

Results

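Gene expression was measured on 18 arrays of TC32 and TC71, cell lines from Ewing sarcoma, a bone and soft tissue tumour driven by the fusion protein EWS-FLI1. YK-4-279 is a small molecule described as blocking the binding of EWS-FLI1 to RNA helicase A, the product of DHX9. Each line gave 3 arrays of parental cells, 3 of cells kept in 3 µM YK-4-279 for 72 h, and 3 of clones selected for resistance to it. Expression values are log2 relative to the median of the 18 arrays, and group values are means ± SD with n = 3 arrays. Each group has 3 arrays, and their number limits the precision.

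Arrays of a group were not equally alike. Over 3317 probe sets with an SD above 0.5, TC71 72 h replicates 1 and 3 were the closest pair, with a root mean square difference of 0.28. TC32 parental replicate 1 was closest to TC71 parental replicate 1, at 0.71. It differed by 0.76 on average from the TC71 parental arrays and by 1.09 from the other TC32 parental arrays, which differed from each other by 0.54. LPL, which encodes a lipase, stood at 4.24 in TC32 parental replicate 1 and between -0.07 and -0.01 in the other TC32 arrays. TC71 parental replicate 2 was closest to TC71 72 h replicate 1, at 0.69. Interferon genes set 3 arrays apart. Relative to the parental mean of the line, their list median was 3.81 in TC71 72 h replicate 2, 3.58 in TC32 clone C4 and 1.38 in TC71 clone C4A, against 0.81 and 0.78 in the other TC71 72 h arrays.

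**Figure D1:**
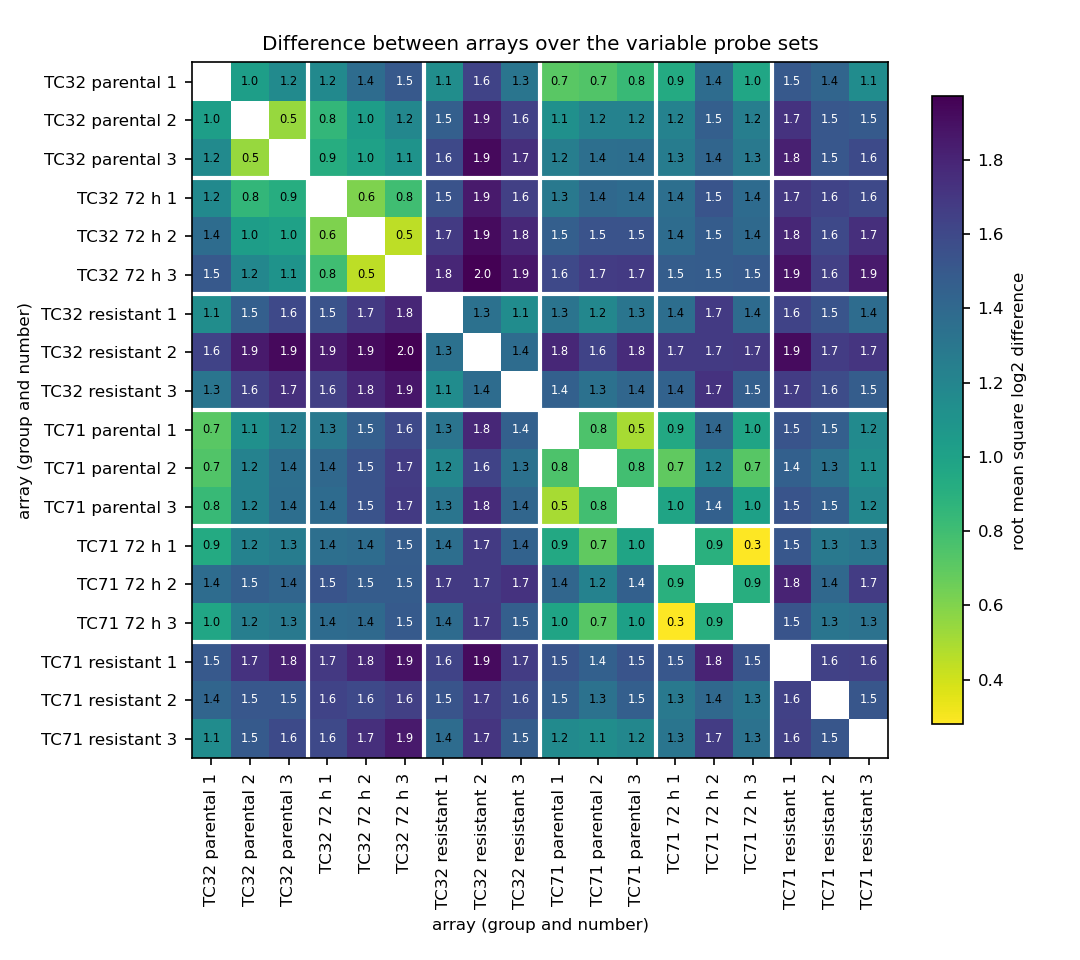
Root mean square log2 difference between each pair of the 18 arrays over 3317 probe sets with an SD above 0.5.

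The first comparison asked which genes responded to 72 h of the compound in TC32. TRIM48, a gene of the tripartite motif family, stood at 5.04 ± 0.37 in the treated arrays and at 0.00 ± 0.01 in the parental arrays (adjusted p = 5.53e-11). PRAMEF12, of the PRAME family active in germ cells and early embryos, stood at 6.49 ± 0.94 against 0.32 ± 0.38 (adjusted p = 3.96e-07). MC1R, the melanocortin receptor, stood at 5.34 ± 0.81 against 0.05 ± 0.09 (adjusted p = 1.93e-07), and the dehydrogenase gene DHRS2 at 5.76 ± 0.55 against -0.34 ± 0.15 (adjusted p = 0.00446). FAP, a surface protease of mesenchymal cells, fell to -4.04 ± 0.62 from -0.25 ± 0.61 (adjusted p = 0.00387). In the array annotation TRIM48 (220534_at) lies on chromosome 11 at 55029657-55038594 and its probe set has 5 alignments, PRAMEF12 (216001_at) on chromosome 1 at 12834999-12838049, MC1R (205458_at) on chromosome 16 at 89984286-89987385, and FAP (209955_s_at) on chromosome 2 at 163027453-163099885.

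In all, 145 genes rose and 136 fell at 72 h in TC32, and 12469 of 12750 did not pass. Of the 281, 106 changed at least 2-fold. KHDC1L rose by 6.42 (standard error, SE, 1.31; adjusted p = 0.0273), but its parental arrays stood at -0.07, 6.86 and 6.95. Other named falls were ZNF23 (-2.28, adjusted p = 0.0302), HDGFL3 (-1.99, adjusted p = 0.0138), ARMCX2 (-1.89, adjusted p = 0.00408) and KYAT1 (-1.74, adjusted p = 0.0303). The ribosomal gene RPL14 (-0.80, adjusted p = 0.0383) also fell. Groups did not overlap at 20.2% of genes, where 10% come by chance. The count was 673, 94 and 68 without 72 h replicates 1, 2 and 3, and 90 and 152 without parental replicates 2 and 3. ARMCX2, DHRS2, FAP, MC1R, PRAMEF12 and TRIM48 passed whichever array was left out, while the highest adjusted p was 0.0669 for HDGFL3, 0.113 for KHDC1L, 0.13 for ZNF23, 0.149 for KYAT1 and 0.179 for RPL14. A fit of the 6 compared arrays alone gave 171 genes and kept 8 of the 12 genes that the naming rule gave. Over the settings other than leaving out 1 array, adjusted p reached at most 0.00795 for TRIM48, 0.025 for MC1R and 0.0278 for PRAMEF12. The count was far higher with array weights and also higher with replicate number as a block, as given below with the other settings.

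Gene lists asked whether whole programmes moved. DNA replication genes stood lower at 72 h in TC32, with a median change of -0.48 over 59 genes (camera, adjusted p = 1.07e-14), and the ribonucleotide reductase genes RRM1 (-1.06, adjusted p = 0.0471) and RRM2 (-1.21, adjusted p = 0.032) fell. The test no longer passed with an estimated correlation (adjusted p = 0.689), as for every list of this comparison. Adjusted over the list alone, 19 replication genes fell and 1 rose. G2/M genes also stood lower (median -0.29, adjusted p = 8.8e-05, 0.689 with an estimated correlation), with 0 of 67 past the limma threshold and 15 at an unadjusted p under 0.05. Stress response genes stood higher (median 0.42 over 38 genes, adjusted p = 0.00236, 0.689 with an estimated correlation), and DNAJC3, a chaperone cofactor gene, rose by 1.33 (adjusted p = 0.013). It was also the only member past the threshold adjusted over the list alone. Immediate early genes stood higher by a median of 0.17 (adjusted p = 0.00377, 0.689 with an estimated correlation), with 0 of 34 past the limma threshold and 6 at an unadjusted p under 0.05. Ribosomal protein genes stood lower (median -0.08, adjusted p = 3.92e-06, 0.689 with an estimated correlation), where RPL12, RPL14, RPL15 and RPS21 were among those that fell, and 15 fell and 1 rose adjusted over the list alone.

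The other 14 lists had adjusted p between 0.0557 and 0.834. Among their 503 genes VCAN rose by 0.85 (adjusted p = 0.0105), and INA (adjusted p = 0.0151) and L1CAM (adjusted p = 0.0195) also rose, while CALCB and SESN1 fell. For p53 targets the median (-0.05) and the mean (0.03) differed in sign, and for apoptosis regulators the mean was 0.03 while the test pointed down. Of these 14, 5 passed without some array, most often the splicing list (3 of 6 fits, lowest adjusted p = 0.0102). Only the replication list kept its call whichever array was left out. The G2/M list reached an adjusted p of 0.104 without 72 h replicate 3 (median -0.06) and 0.0554 without parental replicate 1. The stress response list reached 0.424 and 0.358 without the same 2 arrays, the immediate early list 0.0554 without parental replicate 1, and the ribosomal list 0.228 without 72 h replicate 1. Relative to the parental mean, stress response medians were 0.01, 0.45 and 0.88 in the treated arrays and -0.71, 0.19 and 0.51 in the parental arrays.

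The same question in TC71 gave 19 genes in the main setting. Untreated parental replicate 2 shared shifts of whole chromosome arms with the 72 h arrays, as given below. Differences between cultures may therefore enter the 72 h comparison of TC71. NEFM, a neurofilament gene, rose from 0.01 ± 0.01 to 1.54 ± 0.39 (adjusted p = 0.000254), and APOH, which encodes a plasma apolipoprotein, from 0.33 ± 0.37 to 1.56 ± 0.24 (adjusted p = 0.00589). SESN1, a sestrin gene driven by p53, fell from 0.34 ± 0.20 to -0.54 ± 0.12 (adjusted p = 0.0319). NEFM (205113_at) lies on chromosome 8 at 24771306-24776606 and SESN1 (218346_s_at) on chromosome 6 at 109307646-109415277.

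At 72 h in TC71, 10 genes rose and 9 fell, and 12731 did not pass, while 1347 had an unadjusted p under 0.05 where 638 come by chance. B3GNT2 rose by 0.99 (adjusted p = 0.000707) and CTAG2 by 1.22 (adjusted p = 0.0144). The CTAG2 value rests on probe set 215733_x_at (2.42), and 207337_at gave 0.03. TEFM (-0.70, adjusted p = 0.034), STAG2 (-0.66, adjusted p = 0.0455), EP400 (-0.65, adjusted p = 0.0314) and RPS21 (-0.61, adjusted p = 0.0455) fell. Groups did not overlap at 25.2% of genes against 10% by chance. The count was 5 and 10 without 72 h replicates 1 and 3, and 5, 41 and 5 without parental replicates 1, 2 and 3. APOH, B3GNT2 and NEFM passed whichever array was left out, and the highest adjusted p was 0.0781 for CTAG2, 0.164 for EP400, 0.18 for TEFM, 0.184 for SESN1, 0.221 for RPS21 and 0.225 for STAG2. A fit of the 6 arrays alone gave 290 genes and kept 6 of the 10 genes that the naming rule gave. The count was also 476 after quantile normalization again (39.1% higher against 52.6%), 447 with replicate number as a block and 3012 with array weights. It fell with TC71 72 h replicates 1 and 3 averaged, with trend and robust empirical Bayes, and without _x_at and _s_at probe sets. Of the 10 named genes averaging kept 4, and trend and robust settings kept 5. The number of genes in TC71 thus depends on the setting.

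**Figure D2:**
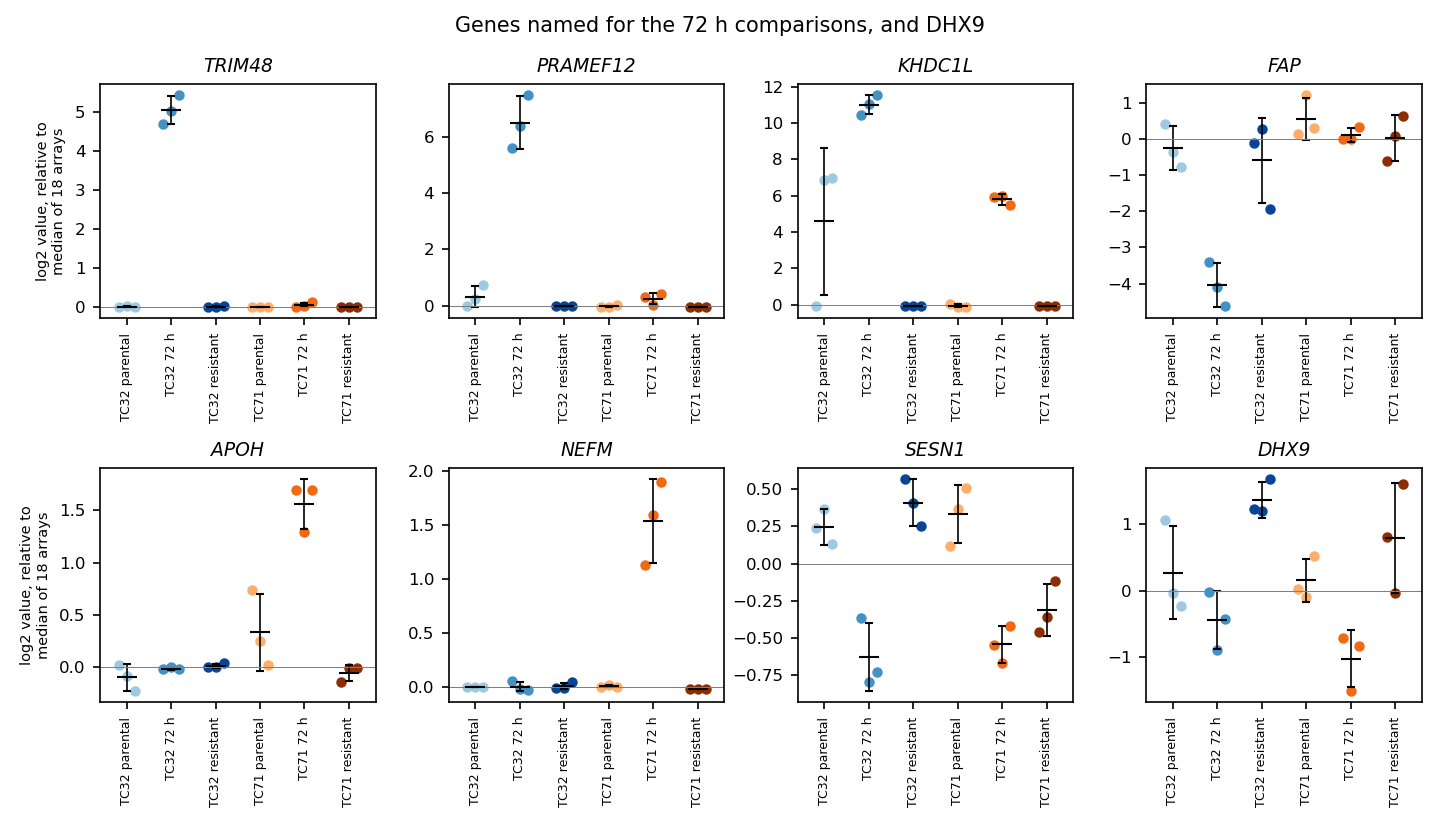
Values of 8 genes in each array with group means ± SD (n = 3), log2 relative to the median of the 18 arrays.

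Stress response genes also stood higher at 72 h in TC71. Their median change was 1.23, with 37 of 38 genes higher (camera, adjusted p = 7.61e-19, 0.269 with an estimated correlation). DDIT3, a transcription factor of the integrated stress response, stood 3.89 higher (adjusted p = 0.176), and TRIB3 and CHAC1 stood 3.47 higher, so 0 passed the limma threshold over all genes. Adjusted over the list alone 18 rose, and 26 had an unadjusted p under 0.05. Replication genes stood lower (median -0.42, adjusted p = 3.61e-22, 0.269 with an estimated correlation), with 0 past the limma threshold over all genes, 7 adjusted over the list alone and 24 at an unadjusted p under 0.05. G2/M genes stood lower (-0.34, adjusted p = 8.87e-16, 0.361 with an estimated correlation), with 0 over all genes, 3 adjusted over the list alone and 16 unadjusted.

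All 41 interferon genes stood higher at 72 h in TC71 (median 1.47, adjusted p = 4.45e-09, 0.416 with an estimated correlation), but 0 passed in limma and 5 had an unadjusted p under 0.05. Without 72 h replicate 2 the median was 0.80 (adjusted p = 0.00053). Splicing genes stood lower (-0.13, adjusted p = 2.53e-06, 0.269 with an estimated correlation), with 2 past the threshold adjusted over the list alone, 0 over all genes and 10 unadjusted. Heat shock genes stood lower (-0.19, adjusted p = 0.000852, 0.416 with an estimated correlation), with 0 members past limma and 5 unadjusted. Extracellular matrix genes stood higher by 0.03 (adjusted p = 0.0342, 0.361 with an estimated correlation) with 1 member past the threshold adjusted over the list alone, 0 over all genes and 3 unadjusted. Hypoxia genes stood higher by 0.09 (adjusted p = 0.0468, 0.361 with an estimated correlation) with 0 members past limma and 8 unadjusted. The other 11 lists had adjusted p between 0.0625 and 0.976, and of their 404 genes NEFM rose while SESN1 and RPS21 fell. The median and mean differed in sign for p53 targets (-0.05 and 0.16) and for EWS-FLI1 activated targets (0.07 and -0.03), and the mean of the markers of other cell types was -0.01 while the test pointed up. Of these 11, 5 passed without some array, most often the immediate early list (2 of 6 fits, lowest adjusted p = 0.00467). The extracellular matrix list reached an adjusted p of 0.065 without 72 h replicate 3, 0.0742 without parental replicate 1 and 0.0737 without parental replicate 3. The hypoxia list reached 0.106 and 0.178 without 72 h replicates 1 and 3 and 0.0572 and 0.0763 without parental replicates 1 and 3.

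**Figure D3:**
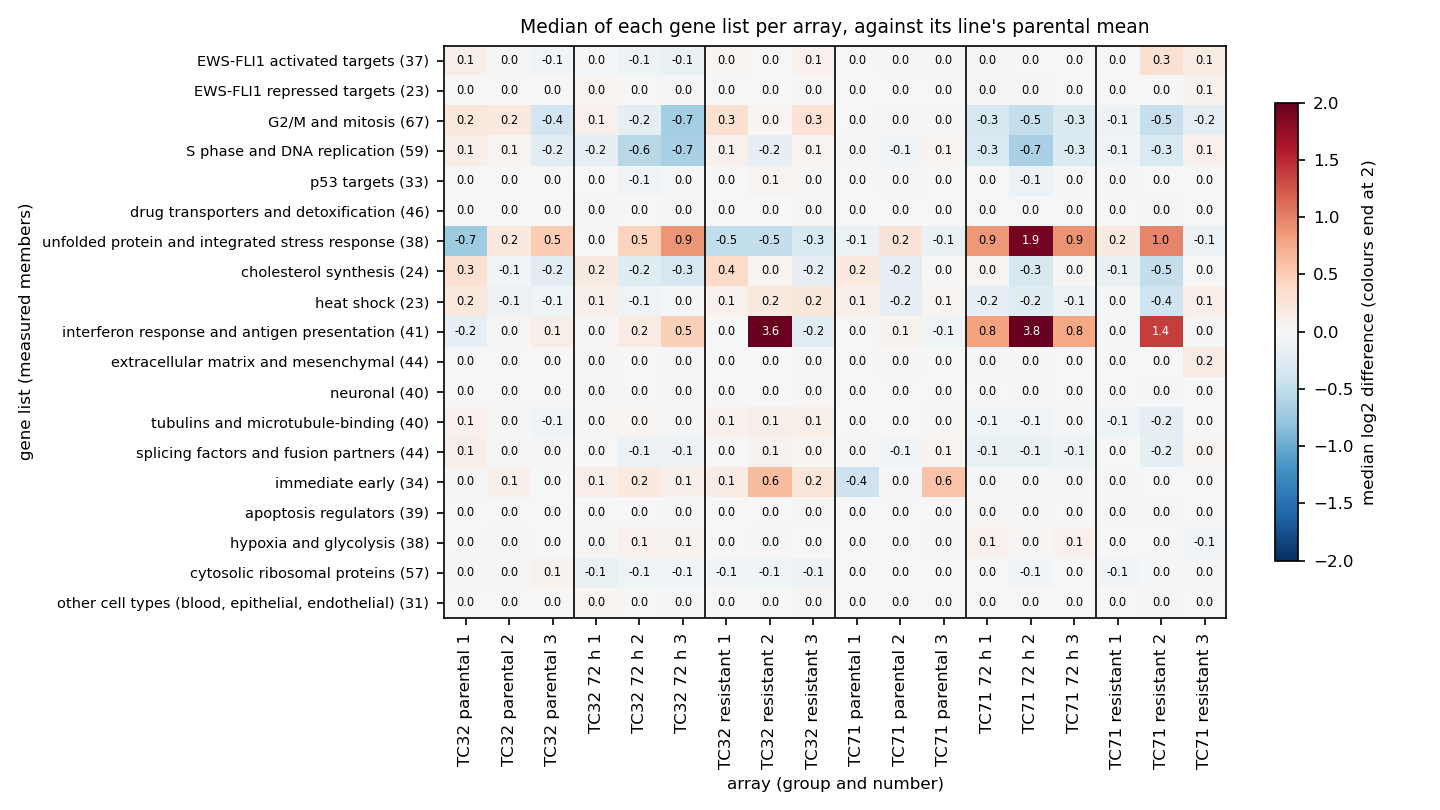
Median of each of the 19 gene lists in each array, relative to the parental mean of its line.

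Clones that grew in the compound were compared with parental cells to find what resistant cells had changed. No untreated cells kept for the same 7 months were measured. Exposure, selection, clonal origin and time in culture therefore cannot be told apart. In TC32, the largest rises included the muscle protein genes TNNT1, MYLK and MYOM2. The troponin gene TNNT1 stood at 1.25 ± 0.83 in the clones and -4.15 ± 2.11 in parental arrays (adjusted p = 0.00325), the myosin kinase gene MYLK at 2.64 ± 0.38 against -1.83 ± 1.81 (adjusted p = 0.00398) and MYOM2 at 1.77 ± 1.20 against -2.60 ± 0.72 (adjusted p = 0.00354). TIMP3, an inhibitor of matrix proteases, rose from -1.54 ± 0.80 to 1.70 ± 0.26 (adjusted p = 0.00106). MAGEA3, a cancer-testis antigen gene, fell from 1.84 ± 2.00 to -7.03 ± 1.55 (adjusted p = 0.00626), and NEFL, a neurofilament gene, from 0.35 ± 0.75 to -5.37 ± 1.20 (adjusted p = 0.00905). MAGEA6 (-8.78, adjusted p = 0.00648), MAGEA12 (-7.98, adjusted p = 0.0162) and MAGEA5P (-6.05, adjusted p = 0.00936) fell, but MAGEA genes are near-identical copies read partly by shared probes (_x_at) and do not count as separate findings. TIMP3 (201147_s_at) lies on chromosome 22 at 33196807-33259030, TNNT1 (213201_s_at) on chromosome 19 at 55644198-55660574 and MAGEA3 (209942_x_at) on chromosome X at 151867264-151870814.

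In resistant TC32, 407 genes rose and 398 fell, 11945 did not pass, and 301 changed at least 2-fold. TMSB15B rose by 4.39 (adjusted p = 0.0356) and the zinc finger gene ZNF83 by 4.06 (adjusted p = 0.00387). Groups did not overlap at 21.2% of genes against 10% by chance. The count was 1214, 277 and 243 without parental replicates 1, 2 and 3, and 431 without clone C4. Of 27 named genes, 12 passed whichever array was left out, among them TIMP3, MAGEA3, NEFL, TNNT1, MYLK and MYOM2. Those that passed were 24, 15 and 12 without parental replicates 1, 2 and 3, and 24, 16 and 17 without clones C1, C4 and CP. The highest adjusted p of the other 15 ran from 0.0505 for SGK1 to 0.166 for TMSB15B. A fit of the 6 arrays alone gave 68 genes and kept only CCN2 and GSTM3 of the 27.

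Among the lists in resistant TC32, ribosomal protein genes stood lower (median -0.10, camera, adjusted p = 1.51e-05, 0.945 with an estimated correlation). Of them 7 fell, among them RPL28 (-0.68, adjusted p = 0.0215) and RPL4 (-0.67, adjusted p = 0.00606), and 10 fell and 1 rose adjusted over the list alone. Immediate early genes stood higher by 0.41 (adjusted p = 0.0022, 0.945 with an estimated correlation). JUN rose by 2.94 (adjusted p = 0.0361), SGK1 by 1.61 (adjusted p = 0.0088), KLF6 by 1.18 (adjusted p = 0.0204) and MCL1 by 0.44 (adjusted p = 0.0348), and 7 rose and 1 fell adjusted over the list alone. Both lists kept their calls whichever array was left out, and without clone C4 the immediate early median was 0.26 (adjusted p = 0.0443). The immediate early list lost its call (adjusted p = 0.205) when the 4 arrays that stood apart were left out.

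The other 17 lists in resistant TC32 had adjusted p between 0.0659 and 0.99, and of their 667 genes 18 rose and 17 fell (25 and 20 adjusted over the list alone). EWS-FLI1 repressed targets included CCN2, a matrix protein gene up by 3.79 (adjusted p = 0.0145), and SPRY1, which fell (-1.70, adjusted p = 0.0318). EWS-FLI1 activated targets included PDGFC, a growth factor gene that fell (-2.12, adjusted p = 0.00325), and ID2, up by 1.44 (adjusted p = 0.0383). CDH11 rose by 1.87 (adjusted p = 0.0159), TUBB2A by 1.40 (adjusted p = 0.0162), MAP4 by 1.18 (adjusted p = 0.0391) and the glutathione transferase gene GSTM3 by 1.87 (adjusted p = 0.0337). CYP26B1 (-1.48, adjusted p = 0.00354) and the apoptosis gene DIABLO (-0.77, adjusted p = 0.00875) fell. With 1 array left out 4 of the 17 lists passed at least once. The G2/M list (median 0.20) passed in 4 of 6 fits (lowest adjusted p = 0.000207, medians 0.00 to 0.30). The interferon list (0.78) passed in 3 of 6 (lowest adjusted p = 2.75e-06, medians -0.10 to 1.67). Stress response (0.00316) and heat shock genes (0.0084) passed without parental replicate 1. When the 4 arrays that stood apart were left out, the G2/M list stood higher (0.34, adjusted p = 0.00173) and the interferon list lower (-0.19, adjusted p = 0.0283). These calls use the preset correlation. With an estimated correlation and all arrays, 0 of the 19 lists passed in resistant TC32 (camera, lowest adjusted p = 0.945).

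In TC71 clones, AKR1C3, a carbonyl-reducing enzyme gene, rose from -0.83 ± 0.79 to 4.15 ± 1.50 (adjusted p = 0.00603). MGP, which encodes a matrix protein that prevents calcification, rose from 0.16 ± 0.83 to 4.97 ± 0.97 (adjusted p = 0.00657), and the transporter gene ABCA8 from -2.09 ± 1.01 to 1.87 ± 0.37 (adjusted p = 0.0017). TIMP3 rose from -0.61 ± 0.63 to 2.30 ± 0.53 (adjusted p = 0.00454). LPL fell from 7.15 ± 0.28 to 0.43 ± 0.90 (adjusted p = 0.00431). AKR1C3 (209160_at) lies on chromosome 10 at 5136597-5149878, MGP (202291_s_at) on chromosome 12 at 15034827-15038768 and LPL (203548_s_at) on chromosome 8 at 19796752-19824769.

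In resistant TC71, 58 genes rose and 81 fell, 12611 did not pass, and 67 changed at least 2-fold. TRIM68 rose by 3.32 (adjusted p = 0.046). DNAJC15, a mitochondrial cochaperone gene, fell by 4.07 on the log2 scale (adjusted p = 0.0186), and MEIS2 (-3.91), ZNF83 (-2.94) and TSPAN7 (-2.77) also fell (adjusted p = 0.046 for each). Groups did not overlap at 41.2% of genes against 10% by chance. That share does not count changed genes, since small offsets of whole arrays can part the groups. Probe sets with an SD under 0.05 had medians of -0.0132, -0.0117 and -0.0078 in the clones. In the parental arrays these medians were 0.0032, -0.004 and 0.0015. The count was 19 and 25 without parental replicates 1 and 3, and 408 without clone C5. ABCA8, AKR1C3, CCND1, LPL and TIMP3 passed whichever array was left out. The highest adjusted p was 0.0511 for MGP, 0.109 for ZNF83, 0.114 for DNAJC15, 0.164 for MEIS2, 0.171 for TRIM68 and 0.188 for TSPAN7. In a fit of the 6 arrays alone 0 genes passed in limma (lowest adjusted p = 0.0633), with 1793 at an unadjusted p under 0.05.

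**Figure D4:**
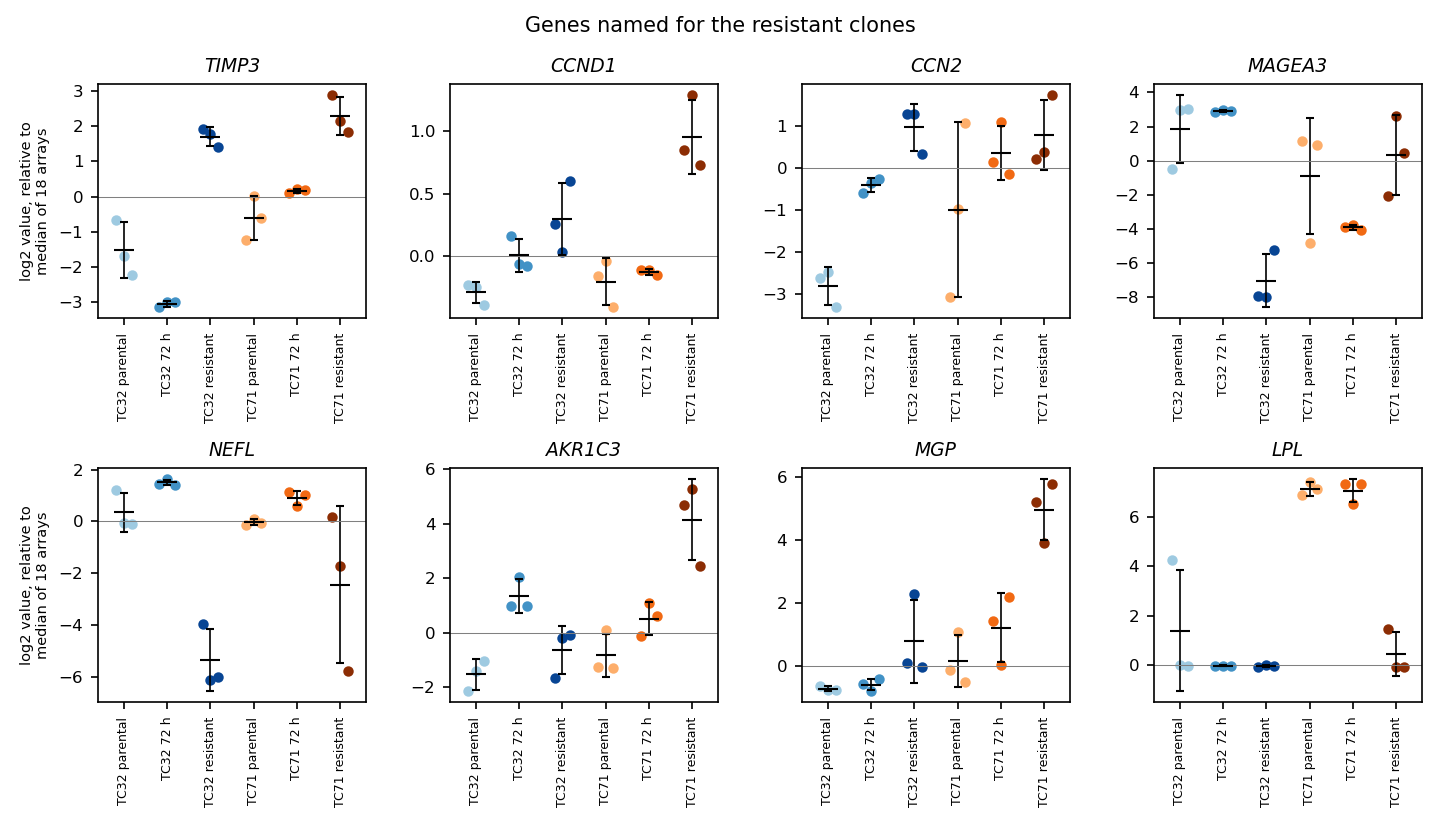
Values of 8 genes in each array with group means ± SD (n = 3), log2 relative to the median of the 18 arrays.

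Of the 19 lists, 6 passed in resistant TC71. EWS-FLI1 activated targets stood higher by a median of 0.16 (camera, adjusted p = 0.000456, 0.251 with an estimated correlation), of which CCND1 rose, and 4 rose adjusted over the list alone. Extracellular matrix genes stood higher by 0.05 (adjusted p = 0.00167, 0.251 with an estimated correlation), of which ACTA2 and TIMP3 rose, and 4 rose adjusted over the list alone. Stress response genes stood higher by 0.35 (adjusted p = 0.000456, 0.855 with an estimated correlation), with 0 past limma and 4 unadjusted. G2/M genes stood lower (-0.27, adjusted p = 0.000994, 0.89 with an estimated correlation), with 0 past limma and 9 unadjusted. Interferon genes stood higher by 0.26 (adjusted p = 0.017, 0.89 with an estimated correlation), with 0 past limma and 2 unadjusted, and EWS-FLI1 repressed targets by 0.03 (adjusted p = 0.0446, 0.674 with an estimated correlation), with 0 past limma and 4 unadjusted.

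The other 13 lists in resistant TC71 had adjusted p between 0.102 and 0.858, with 2 genes up and 4 down of 508 (4 and 8 adjusted over the list alone). Neuronal genes had a median of -0.01 and a mean of 0.12, immediate early genes -0.01 and 0.07, and markers of other cell types -0.01 and 0.01. Of these 13, 3 passed without 1 array, with the lowest adjusted p for immediate early genes (1.73e-05, without parental replicate 3). Clone C4A carried most of the 6 calls. Without it the adjusted p was 0.142 for activated targets, 0.479 for G2/M and for stress response genes, 0.759 for interferon genes (median -0.02) and 0.0527 for repressed targets. Repressed targets also reached 0.152 and 0.0864 without parental replicates 1 and 2 and 0.327 without clone C5 (median -0.01), and extracellular matrix genes 0.093 without clone C5 (median -0.01).

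The 2 lines were then compared for shared changes. At 72 h, 2 genes fell in both lines (RPS21 and SESN1), where 0.10 were expected (Fisher exact p = 0.00387), and 0 rose in both (expected 0.11). Only CTAG2 passed in opposite directions at 72 h. In the clones, 21 genes rose in both lines (expected 1.85, Fisher exact p = 2.61e-17) and 17 fell in both (expected 2.53, Fisher exact p = 3.72e-10), and 3 moved in opposite directions. The Fisher test takes genes as independent, but 7 of the 16 shared falls with a position lie on chromosome arm 13q. Genes of 15q also stood lower in clones of both lines (medians -0.58 in TC32 and -0.28 in TC71), so arm-wide shifts carry part of this overlap. The shared rises included the clusterin gene CLU, up by 1.64 in TC32 (adjusted p = 0.00118) and 0.96 in TC71 (adjusted p = 0.0433), the galectin gene LGALS3, up by 0.76 (adjusted p = 0.0194) and 1.45 (adjusted p = 0.00268), and TIMP3. Across all genes, which are not independent replicates, changes in the 2 lines correlated at 0.37 at 72 h and 0.23 in the clones. The shared count at 72 h was 8 without TC32 72 h replicate 1, stayed at 2 without TC32 parental replicate 1, and was 0 or 1 without any other array. The shared count in clones was 19 and 17 without TC32 parental replicates 2 and 3, 9 and 11 without TC71 parental replicates 1 and 3, and 62 and 100 without clones C4A and C5.

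Interactions asked which changes differed between the lines. At 72 h 48 genes passed and in the clones 30, of 12750. With 1 array left out the first count ran from 18 (without TC71 parental replicate 3) to 100 (without TC32 72 h replicate 1), and the second from 6 (without TC71 parental replicate 1) to 289 (without TC32 parental replicate 1). PRAMEF12 rose more in TC32 by 5.90 (adjusted p = 3.77e-05), MC1R by 5.28 (adjusted p = 1.4e-05) and TRIM48 by 4.99 (adjusted p = 5.09e-09), and the values for DHRS2 (4.66, adjusted p = 0.207) and FAP (-3.36, adjusted p = 0.106) did not pass. NEFM (-1.53, adjusted p = 0.00137) and B3GNT2 (-0.94, adjusted p = 0.00799) rose more in TC71. CTAG2 fell in TC32 (-1.02, adjusted p = 0.00907) and rose in TC71 (interaction -2.24, adjusted p = 0.000716). For the clones, ZNF83 differed by 7.01 (adjusted p = 0.00657). ABCA8 differed by -4.06 (adjusted p = 0.0193, at most 0.0653 with 1 array left out). The falls of MAGEA3 (-10.14, adjusted p = 0.0827) and LPL (5.29, adjusted p = 0.103) and the rises of AKR1C3 (-4.09, adjusted p = 0.113) and TIMP3 (0.32, adjusted p = 0.833) did not pass this test. Verdicts on 3 of these genes depended on single arrays. The TC32 part of the LPL value came from parental replicate 1 alone (4.24), and without that array LPL differed by 6.72 (adjusted p = 7.59e-05) and MAGEA3 by -11.29 (adjusted p = 0.0253). MAGEA3 also passed without clone C3 of TC71 (adjusted p = 0.0474) and AKR1C3 without clone C5 of TC71 (-4.94, adjusted p = 0.0149), while DHRS2, FAP and TIMP3 did not pass whichever array was left out. Without probe sets with the suffixes _x_at and _s_at CTAG2 gave 0.03 in TC71 (adjusted p = 1) and an interaction of -0.04 (adjusted p = 1), so its calls rest on the _x_at probe set.

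Resistant clones were also compared with cells at 72 h. This does not separate long from short exposure, since clones also differ in selection, clonal origin and months of culture. The compound may also have been absent at their harvest. In TC32, 947 genes rose and 943 fell, and in TC71, 183 and 136. KHDC1L (-11.08, adjusted p = 0.000313), MAGEA3 (-9.93, adjusted p = 0.00153) and MAGEA6 (-9.57, adjusted p = 0.00184) stood lower in TC32 clones than at 72 h. TNNT1 stood 6.88 higher (adjusted p = 0.00027), TMSB15B 6.26 higher (adjusted p = 0.00305) and MYOM2 5.67 higher (adjusted p = 0.000284), and all 6 passed whichever array was left out. In TC71, LPL (-6.64, adjusted p = 0.0026) and KHDC1L (-5.89, adjusted p = 0.036) stood lower, and FMO2 (4.39, adjusted p = 0.0467), MGP (3.75, adjusted p = 0.016) and AKR1C3 (3.63, adjusted p = 0.0196) stood higher. Of these only LPL passed whichever array was left out, and the highest adjusted p of the others was 0.0529 for MGP, 0.0844 for AKR1C3, 0.115 for KHDC1L and 0.135 for FMO2. The count was 1134 and 991 without TC32 72 h replicates 2 and 3, and in TC71 119, 164 and 114 without 72 h replicates 1, 2 and 3 and 533 without clone C5.

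Replication genes stood higher in TC32 clones than at 72 h (median 0.45, camera, adjusted p = 3.46e-06), and so did G2/M genes (0.42, adjusted p = 3.46e-06), while stress response genes stood lower (-0.76, adjusted p = 0.000138). The adjusted p was 0.832 for all with an estimated correlation. In all, 12 replication and 13 G2/M genes rose and 6 stress response genes fell, among them ATF4 (19, 17 and 6 adjusted over the list alone). The other 16 lists had adjusted p between 0.247 and 0.763, with 52 rises and 37 falls in 594 genes. In TC71, replication genes stood higher (0.36, adjusted p = 1.13e-12, 0.542 with an estimated correlation), and HELLS and USP1 rose. Stress response genes stood lower (-0.78, adjusted p = 0.000125, 0.827 with an estimated correlation), with 0 past limma and 9 unadjusted. Splicing genes stood higher (0.07, adjusted p = 0.00118, 0.542 with an estimated correlation), and DDX17, DHX9, SF3B1, SRSF7 and U2AF2 rose. EWS-FLI1 activated targets stood higher (0.10, adjusted p = 0.00133, 0.265 with an estimated correlation), where CALCB, CCND1 and PRKCB rose. G2/M genes (0.09, adjusted p = 0.00169, 0.827 with an estimated correlation) had 0 past limma and 10 unadjusted, and p53 targets (0.05, adjusted p = 0.0249, 0.19 with an estimated correlation) had 1 that fell, CYFIP2. Interferon genes stood lower (-0.99, adjusted p = 0.026, 0.827 with an estimated correlation), with 0 past limma and 3 unadjusted. The other 12 lists had adjusted p between 0.0803 and 0.968. Of the lists that did not pass, 3 of 16 in TC32 and 1 of 12 in TC71 passed without some array. With 1 array left out, the replication lists of both lines and the TC32 G2/M list kept their calls. In TC32 the stress response list reached an adjusted p of 0.0672 without 72 h replicate 3. In TC71 the interferon list reached 0.674 without 72 h replicate 2 (median -0.15), 0.191 without clone C3 and 0.487 without clone C5. The stress response list reached 0.0672 and 0.0771 without 72 h replicate 2 and clone C5, and the G2/M list 0.0741, 0.0854 and 0.0771 without 72 h replicate 2 and clones C3 and C5. Activated targets reached 0.185 without clone C4A, p53 targets 0.203 (median -0.04) and 0.0513 without clones C4A and C5, and splicing genes 0.0669 without clone C5.

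Genes tied to the compound's target and to drug export were followed in every comparison. DHX9 (212105_s_at and 2 other probe sets; chromosome 1 at 182808466-182857115) differed by -0.72 and -1.18 at 72 h in TC32 and TC71 (adjusted p = 0.523 and 0.299), and by 1.10 and 0.64 in their clones (adjusted p = 0.153 and 0.661). With 1 array left out DHX9 passed in resistant TC32 in 1 of 6 fits (adjusted p = 0.0428). It was higher in clones than at 72 h by 1.82 (SE 0.42) in both lines (adjusted p = 0.0123 in TC32 and 0.0429 in TC71). That call was lost in TC32 without 72 h replicate 2 (adjusted p = 0.0577). In TC71 it was lost without 72 h replicates 1, 2 and 3 (adjusted p = 0.0902, 0.135 and 0.103), without clones C3 and C5 (adjusted p = 0.0908 and 0.0893), and in a fit of the 6 arrays alone (adjusted p = 0.329). EWSR1 and FLI1 changed by -0.18 to 0.24 (adjusted p between 0.368 and 1). CCND1, the cyclin D1 gene, rose in clones of TC32 by 0.59 (adjusted p = 0.0413) and of TC71 by 1.16 (adjusted p = 0.00497), and the difference between the lines did not pass (-0.57, adjusted p = 0.308). The TC32 call was lost without any array but clone C4 (adjusted p up to 0.164, without parental replicate 3), while the TC71 call was kept. CCND1 (208711_s_at and 1 other) lies on chromosome 11 at 69455937-69466227. The efflux pump gene ABCB1 stood 1.60 higher at 72 h in TC32 (adjusted p = 0.155) and 0.67 higher in TC71 (adjusted p = 0.839), and differed by 0.00 and -0.11 in the clones (adjusted p = 1 and 0.925). IGFBP3 stood 1.87 higher in TC32 clones (adjusted p = 0.052) and CDKN1A 1.21 higher at 72 h in TC71 (adjusted p = 0.472). For ABCC1, ABCG2, NR0B1, NKX2-2, CD99 and TUBB3 adjusted p lay between 0.0677 and 1 in all comparisons with parental cells.

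Within a line, the change at 72 h was set against that of the clones, to see whether clones kept the early response. In TC32 the correlation was 0.06, below the 0.50 simulated for unchanged groups that share parental arrays, and the covariance was 0.0131 against a simulated 0.0299-0.0421. In TC71 the correlation was 0.35, also below a simulated 0.50, and the covariance was 0.0555 against 0.0315-0.0440. The simulations pooled the spread of all groups and did not match the parental spread of each line. Real changes can also lower the correlation, so the simulations do not decide whether clones kept the early response. In both TC32 comparisons 13 genes rose and 12 fell (expected 4.63 and 4.25, Fisher exact p = 0.000751 and 0.00113), and 9 moved in opposite directions. In TC71 TMEM248 rose in both (Fisher exact p = 0.0446), and KCNH2 and SESN1 fell in both (Fisher exact p = 0.00139). Shared parental arrays add to such overlaps. The correlation was 0.25 in TC32 without parental replicate 1, and in TC71 0.48 without parental replicate 2 and 0.16 without clone C4A.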

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

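The tests of TC32 parental replicate 1, of array-wide normalization for 13q and of another subline at 72 h, and the lists with 1 array left out, were chosen only after results were seen, and the others in this part were written before their results.

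Counts of genes whose change differed between the lines were 48 at 72 h and 30 in the clones. When arrays were regrouped at random within each line, 2 of 100 groupings reached 48 and 6 reached 30, the real one among them each time. The highest regroupings gave 380 and 123 genes, several times the real counts. Regroupings could include the real groups with the labels of 1 line swapped, which adds the changes of the lines. What gave the highest counts was not tested. The resistant count is not set apart from random groupings, a few of which gave as many genes. For genes shared between lines, 1 of 100 regroupings, the real one, reached the 2 genes at 72 h (highest other 1). Likewise 1 of 100 reached the 38 genes in the clones (highest other 1). This cannot decide whether the overlap is random, since regrouped arrays called too few genes to share many. Other splits of a single comparison called at most 6 and 1 genes at 72 h in TC32 and TC71 and 3 and 3 in their clones.

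Splits of the 6 arrays of a single comparison are 10, too few for a share under 0.05 (the smallest is 0.1), and only 1, the real one, reached each count. The real count and the highest other were 281 and 6 at 72 h in TC32, 19 and 1 at 72 h in TC71, 805 and 3 in resistant TC32, and 139 and 3 in resistant TC71. For resistant against 72 h they were 1890 and 3 in TC32 and 319 and 25 in TC71.

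Some genes changed differently at 72 h in the 2 lines. The difference was 5.90 for PRAMEF12, 5.28 for MC1R and 4.99 for TRIM48, whose rises were confined to TC32, and TRIM48 stood only 0.05 higher in TC71. ZNF23 differed by -3.94 (adjusted p = 0.0314) and ARMCX2, an armadillo-repeat gene, by -2.12 (adjusted p = 0.0438). CTAG2, a cancer-testis antigen gene, differed by -2.24, but by -0.04 (adjusted p = 1) without _x_at and _s_at probe sets. NEFM differed by -1.53, APOH by -1.14 (adjusted p = 0.0454) and B3GNT2 by -0.94. ARMCX2 lost its call without any of the 12 arrays (adjusted p between 0.0519 and 0.128), and ZNF23 reached 0.106.

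In the clones, the zinc finger genes ZNF83 and ZNF177 differed by 7.01 and 4.43 (adjusted p = 0.00657 for both). ZNF83 rose in TC32 and fell in TC71. The histone gene H2BC21 differed by 4.16 and the amino acid carrier gene SLC38A4 by -4.14 (adjusted p = 0.0269 for both), and the highest adjusted p with 1 array left out was 0.0827 and 0.0863. TNFAIP6, an inflammation-induced matrix gene, differed by -5.28 (adjusted p = 0.00343). ABCA8 differed by -4.06, PDGFC by -2.87 (adjusted p = 0.0267) and CYP26B1, which breaks down retinoic acid, by -1.98 (adjusted p = 0.0269).

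Gene lists also differed between the lines at 72 h with the preset correlation. Adjusted p was 0.0427 for G2/M (median difference 0.12), 0.00022 for stress response (-0.84), 0.0112 for heat shock (0.16), 0.00463 for interferon genes (-1.17), 0.00355 for immediate early genes (0.44) and 0.00463 for ribosomal proteins (-0.05), and between 0.0613 and 0.884 for the other 13. In the clones it was 9.6e-06 for G2/M (0.42) and for stress response (-0.93), 0.047 for heat shock (0.32) and 0.0018 for ribosomal proteins (-0.04), and between 0.0604 and 0.979 for the other 15. At 72 h each of the 6 lost its call without some array. Interferon genes reached 0.543 without TC32 72 h replicate 1 and 0.329 without TC71 72 h replicate 2 (median -0.32), stress response 0.543 and 0.107 without the same arrays, and immediate early genes 0.296 (0.03) without TC71 parental replicate 3. G2/M genes reached 0.742 without TC32 parental replicate 3, heat shock 0.136 without TC71 72 h replicate 2, and ribosomal proteins 0.83 without TC32 72 h replicate 1. In the clones G2/M and stress response kept their calls (0.22 for G2/M without TC32 parental replicate 3 and -0.47 for stress response without clone C4A of TC71), and heat shock reached 0.408 without that clone and ribosomal proteins 0.137 without TC32 clone CP. Of the lists that did not pass, 2 of 13 at 72 h and 5 of 15 in the clones passed without some array. With an estimated correlation 0 lists passed in camera, with adjusted p from 0.878 to 0.944 and from 0.752 to 0.813 for those named.

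Probe sets with no gene or several genes were tested apart. Of 1841, 52 passed in limma at 72 h in TC32, 4 at 72 h in TC71, 19 in resistant TC32 and 0 in resistant TC71, where 110 had an unadjusted p under 0.05.

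TC32 parental replicate 1 lay nearer to TC71 parental arrays than to its own group. At genes that part the lines it lay beyond all TC71 arrays towards TC32 at 48.7% (19 of 39), no more than the 55.2% of TC71 72 h replicate 2 when left out, which leaves TC71 cells under a TC32 label possible. The other TC71 arrays reached at most 43.8%, the parental ones 32%, 26.1% and 18.2%, and the other TC32 arrays at least 65.5%. TC32 parental replicate 1 lay between these. A left-out TC71 array was held against fewer TC71 arrays than a TC32 array was, so the shares are not like for like and do not decide. A mixture of TC71 RNA with RNA of cells like replicates 2 and 3 could not be told apart, since genes those replicates hold over TC71 stood at a median of -3.99 but the 90th percentile was -3.28 against the -3.32 that a 10% share would leave. For a TC32 culture closer to the origin of the clones, each clone lay nearer to the array at 71.1% or more of 38 genes, as predicted. But these genes were picked because the array departs from replicates 2 and 3. Other arrays unlike those replicates could also lie nearer to it, and TC71 arrays were not tried. LPL, high in this array but not in the TC32 clones, goes the other way. Which of these explanations holds for the array stays open.

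Genes of chromosome arm 13q stood lower in all 6 clones, with medians of -0.15, -0.52 and -0.50 in TC32 C1, C4 and CP and -0.97, -1.10 and -0.45 in TC71 C3, C4A and C5 (148 genes). Of genes that fell in TC71 clones 48 of 77 with a position lie on 13q (expected 1.51, Fisher exact p = 1.93e-65), and in TC32 20 of 369 (expected 7.22, Fisher exact p = 3.03e-05). These counts restate the lower medians of the same clones and are no separate support. The Fisher test also takes the genes of an arm as independent. After quantile normalization, which moved 13.6% to 42.2% of genes by 0.1 or more, the 13q median lay below 95% of random gene sets in 6 clones. This cannot decide on array-wide normalization, since the method ignores position and could hardly remove a shift of 1 arm. In the median clone 87.5% of 13q genes lay below the parental mean. The medians had all but settled this, since a few strongly lowered genes hardly move a median of 148 genes. A lower dosage of the arm fits, since all 3 parts of the arm stood below 0 in 6 clones. A low median of the whole arm makes this likely whatever its cause, so the test does not decide on dosage. In TC32 C1 the middle part stood at only -0.05. Whether DNA copies were lost could not be measured here, and 13q also stood lower in untreated TC71 parental replicate 2 (-0.12), close to the TC71 72 h arrays (-0.18, -0.17 and -0.17).

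The TC32 72 h arrays could differ from the parental arrays for reasons other than the compound. Arm-wide shifts do not account for the whole, since 14.4% of the called genes lay on shifted arms (3.7% of all placed genes). Still, 4 arms were shifted by 0.15 or more in all 3 arrays, as a culture of another subline might give (0.23 on 10p, 0.29 on 4p, -0.23 on 5p and -0.38 on 9p), and 10p varied between TC71 cultures too, at 0.11 to 0.15 at 72 h, 0.10 in untreated parental replicate 2 and -0.05 to 0.51 in the clones. A response shared with TC71 cannot be told apart, since 9 of 100 groupings, the real one among them, reached the correlation of 0.37 between the lines (highest 0.51). How much of the TC32 response is due to the compound stays open. The same holds in TC71, where untreated parental replicate 2 was closest to 72 h replicate 1. It was shifted like the 72 h group on 16q (0.22 against a group median of 0.19), 13q (-0.12 against -0.16) and 1p (-0.11 against -0.11). On 10p (0.10 against 0.16), 10q (0.08 against 0.15) and 11p (0.07 against 0.15) it was shifted less, the same way.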

How the results depend on the processing

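The probe set with the largest SD, the SD filter, the left-out set of 4 arrays, the averaged TC71 72 h replicates and leaving out arrays for lists and correlations were chosen only after results were seen. Values below are in the order 72 h TC32, 72 h TC71, resistant TC32, resistant TC71, resistant against 72 h TC32 and TC71, and the interactions at 72 h and in clones, where the main counts were 281, 19, 805, 139, 1890, 319, 48 and 30. The cause of a move was not tested unless given.

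At an adjusted p under 0.01 the counts were 61, 4, 246, 34, 834, 62, 16 and 6, with 0 genes shared between lines at 72 h and 8 in clones (2 and 38 in the main setting). With at least 2-fold they were 106, 4, 301, 67, 706, 122 and 30 for all but the last, with 0 and 13 shared. These are stricter by construction. Without _x_at and _s_at probe sets they were 184, 10, 436, 47, 1086, 133, 17 and 12. Only the arrays of the groups compared gave 171, 290, 68, 0, 1034, 14, 164 and 0, with fewer degrees of freedom. Fewer degrees of freedom alone would not raise a count, but these fits also drop the spread of the other groups. Arrays of a group differed from each other by 0.28 to 0.91 (root mean square) at 72 h in TC71 and by 1.52 to 1.65 in its clones. Main p values can therefore be too small for clones and too large at 72 h in TC71. They can also be too small for genes that varied mainly in 1 group, such as TRIM48 at 72 h in TC32. Where 0 passed in limma, 1793 and 1240 genes had an unadjusted p under 0.05.

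Array weights gave 2989, 3012 and 1577 genes at 72 h in TC32 and TC71 and in resistant TC32, 85 in resistant TC71, 136 for resistant against 72 h in TC71 and 2236 for the 72 h interaction. DHX9 passed with array weights at 72 h in TC71 (-1.01, adjusted p = 0.00217) and in TC32 (-0.75, adjusted p = 0.044) and in resistant TC32 (1.32, adjusted p = 0.0417), ABCB1 at 72 h in TC32 (1.39, adjusted p = 0.0109), and CDKN1A at 72 h in TC71 (1.07, adjusted p = 0.0109). Quantile normalization again gave 476 at 72 h in TC71 (39.1% higher against 52.6%), 241 in resistant TC71, 1084 for resistant against 72 h in TC32, and 55 for the resistant interaction (58.2% higher against 43.3%). It gave 34 and 63 shared genes and correlations within a line of 0.23 in TC32 and 0.49 in TC71 (0.06 and 0.35 in the main setting). Centring on each array's median gave 18 genes at 72 h in TC71, 33.3% of them higher.

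Empirical Bayes with trend and robust gave 8 genes at 72 h in TC71, 21 for the 72 h interaction and 1 shared at 72 h. Every probe set tested on its own gave 545 for resistant against 72 h in TC71. Genes with an SD under 0.1 left out gave 57 for the resistant interaction and 1 and 60 shared. TC71 72 h replicates 1 and 3 averaged gave 6, 124 and 21 for 72 h in TC71, resistant against 72 h and the 72 h interaction. The left-out set of 4 arrays gave 187 and 49 at 72 h, 92 and 222 for the interactions, correlations of 0.23 and 0.47, and 2 and 5 lists at 72 h and in clones of TC32 (5 and 2 in the main setting). With estimated correlation 0, 0, 0 and 0 lists passed, against 5, 8, 2 and 6. The probe set with the largest SD moved no count by more than 1.5 times.

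Replicate number as a block gave 547, 447 and 115 genes at 72 h in TC32, TC71 and their interaction. Arrays of the same number correlated at 0.19, 0.01 and 0.33 in TC32 and -0.02, 0.04 and 0.04 in TC71, best with their own number in 3 of 6, so replicates may share only a number.

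With 1 array left out the counts ran 68-673, 5-41, 243-1214, 19-408, 991-1984, 114-533, 18-100 and 6-289, the shared genes 0-8 and 9-100, the correlations 0.01-0.25 and 0.16-0.48, and the lists 2-7, 7-9, 3-5 and 1-7. IGFBP3 passed in resistant TC32 without clone C1 (2.80, adjusted p = 9.53e-16). DHX9 and TUBB3 also passed there in 1 of 6 fits each (lowest adjusted p = 0.0428 and 0.0124). Of 576 calls of named genes with 1 array left out, 405 were kept. Not run were the filter on mean level, which centred values do not allow, and the other table, which was identical.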

Other observations

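The early-embryo list was put together only after results were seen, so its test was chosen only after results were seen, and so were the genes named in this part.

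Several genes active in the early human embryo stood higher in TC32 at 72 h. Besides TRIM48 and PRAMEF12, RFPL1 rose by 3.53 (adjusted p = 1.24e-07), RFPL2 by 5.03 (adjusted p = 4.68e-07) and RFPL3 by 4.20 (adjusted p = 1.2e-06), and all were still past the threshold with any array left out. The pooled spread behind these values takes in other groups, where the RFPL genes varied little. In a limma fit of the 6 compared arrays alone adjusted p was 0.025, 0.0304 and 0.0342. The differences from TC71 were 3.46 (adjusted p = 1.17e-05), 4.97 (adjusted p = 3.77e-05) and 4.03 (adjusted p = 0.000128). KHDC1L, also on the list, does not share this pattern, since it stood at 6.86 and 6.95 in TC32 parental replicates 2 and 3 and at 5.46 to 5.99 in the TC71 72 h arrays (interaction 0.58, adjusted p = 1). RFPL genes are close copies, so shared probes could carry part of this. Of the 2 remaining measured members not picked for their size, 0 passed in limma (CCNA1 2.03, adjusted p = 0.0719, and SLC34A2 1.92, adjusted p = 0.165), so an early embryonic programme cannot be told apart from a few separate genes. CCNA1 does not share the TC32 pattern either, since it stood 1.96 higher at 72 h in TC71 (adjusted p = 0.176, interaction 0.08). CCNA1, the cyclin A1 gene, stood lower in clones than at 72 h in TC32 by 4.39 (adjusted p = 0.000375) and in TC71 by 3.75 (adjusted p = 0.00395). DUX4, which drives such genes in embryos, could be looked for with a targeted assay.

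Some interferon genes stood highest in 2 arrays. IFI27 stood at 9.70 in TC32 clone C4 and 8.58 in TC71 72 h replicate 2, RSAD2 at 8.08 and 6.39, OAS1 at 6.75 and 4.82, and CXCL10 at 8.70 and 5.82. IFI27 (2.62 and 4.29) and CXCL10 (3.01 and 3.42) also stood high in TC32 72 h replicates 2 and 3, and MX1 was flat (0.00 in TC32 clone C4 and 0.03 in TC71 72 h replicate 2). The stress response median was also highest in TC71 72 h replicate 2 (1.91, against 0.87 and 0.90 in the other TC71 72 h arrays). The values do not tell an infection, a density effect or the compound apart.

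In the TC32 clones 5 chromosome arms other than 13q were shifted by 0.15 or more, before rounding, the same way in all 3 arrays. The median change was -0.58 on 15q, 0.37 on 16q, 0.26 on 9q and -0.20 on Xq (gene permutation p = 1e-04, the lowest possible). It was 0.25 on 9p (gene permutation p = 2e-04). These permutations drew random sets of genes and did not permute arrays. They take the genes of an arm as independent and do not measure the spread between clones. The shifts of 2p (0.28), 11p (0.27), 7q (0.22) and 19p (0.21) did not reach a size of 0.15 in every array. Those of 10p (0.16) and 13q (-0.41) missed it narrowly in clone C1 (sizes of 0.1472 and 0.1486). The 16q genes do not single out this line, since they also stood higher in TC71 clones (0.21), at 72 h in TC71 (0.19) and in TC71 parental replicate 2 (0.22). Genes of 15q also stood lower in TC71 clones (median -0.28), though not in clone C4A (0.09). TC32 parental replicate 1 was shifted the same way on 4 of the 5 (16q 0.26, 9q 0.20, 9p 0.13 and Xq -0.15) and less on 15q (-0.07), relative to the mean of the 3 parental arrays that includes it. The 7 genes that fell on 13q in both lines were SAP18, VWA8, STARD13, PIBF1, SLITRK5, EXOSC8 and PSPC1 (expected 0.31, Fisher exact p = 9.43e-09). That Fisher test, too, takes the genes of an arm as independent and restates the lower 13q medians. At 72 h, 13q had a median change of -0.16 in TC71 and -0.11 in TC32, but untreated TC71 parental replicate 2 stood at -0.12 (0.05 and 0.07 in replicates 1 and 3), so the TC71 shift is not tied to the treated cultures. Of the genes that fell in limma at 72 h, 0 lay on 13q, with 0.16 expected in TC71 and 2.33 in TC32. Of those that rose, 1 in TC71 and 7 in TC32 lay on it, against the lower medians.

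TC32 and TC71 parental groups differed at 6 genes, and at 266 when TC32 parental replicate 1 was left out. At 72 h the lines differed at 837 genes and in the clones at 209.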
